A study of Drosophila melanogaster with 14 samples.

How the data were processed

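RNA-seq of 6 wing disc libraries was used, 3 wildtype and 3 nub1. The ATAC-seq and ChIP-seq samples of the series were not analysed here. The values are raw read counts per gene as deposited, with no normalization; per the labels, the libraries were made with a directional RNA kit from dissected discs. Per the submitters' processing notes, the tools bcl2fastq, HISAT2, featureCounts, Bowtie2 and deepTools and the genome build dm6 were used, with no role or version given. The strand setting, the handling of reads mapping to several places and the annotation release are not given in the sources used here, so counts of overlapping, antisense or near-identical genes may be shared.

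Of 17807 gene IDs, 17710 matched a symbol, and the 97 others held 0.687% of the counts. Positions came from the RefSeq annotation of Release 6, the assembly of dm6, for 17672 IDs. Genes passing filterByExpr by group (9186) were scaled by TMM and tested with the edgeR quasi-likelihood test (glmQLFit and glmQLFTest, robust), genotype being the only term, with Benjamini-Hochberg adjustment. A gene was called at adjusted p under 0.05. The SE of a log2 fold change is its size divided by the square root of F. CPM values are TMM-scaled, given as mean ± SD of 3 libraries. Versions were R 4.3.3, edgeR 4.0.16, limma 3.58.1, DESeq2 1.42.0 and matplotlib 3.10.9.

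Before the data were examined, 26 gene lists were fixed, with 290 of 319 members tested. The 2 symbols Med and d were left out, since the ID given for Med is not in the count table and d is a synonym of several genes. Lists were tested with camera at a preset correlation of 0.01, adjusted over the lists, and again with an estimated correlation and with fry. None of the 9 lists called by camera kept its call with an estimated correlation, where 0 lists had an unadjusted p under 0.05 and fry called 15, among them the Hox, Hippo, apoptosis, myoblast, trachea and sex-linked lists that camera did not call. Calls per arm were compared with Fisher's exact test. The genes named are nub, pdm2 and rn, genes from the 10 largest changes per direction among called genes with a mean of at least 5 CPM and no overlap between groups, and up to 4 called members per list with the smallest adjusted p. Where a list had no called member, its 2 most expressed were taken. Other list members, and Ref2, Nepl7, CCT4, bun, lncRNA:CR44596 and lncRNA:CR44595, are named as examples chosen after their values were seen. A fold against a group with no counts uses a floor of 3 counts over the group. Intervals and floors cover counting error only.

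Alternatives were other scalings, filters, tests and thresholds, a replicate block and leaving out each library. Leaving out both libraries numbered 3 was added after seeing the data. Where leaving out a library changed a list's number of called members by over 1.5 times, that number is given with the library, a choice also made after seeing the data. Replicate pairs differed by 4.15 to 32.1 chi-square per degree of freedom, above sampling noise. The highest values, 32.1 and 24.7, were those of nub1 replicate 3 against nub1 replicates 1 and 2, which differed from each other by 4.15. The code was tested on simulated counts for the comparison of nub1 with wildtype, with 9151 genes tested. All genes were given the same dispersion, and 200 genes with a mean of at least 5 CPM were changed. The rates that follow need not hold for the real counts, where more genes were called and lower counts were tested. edgeR recovered 28 of 50 genes changed 1.2-fold and all 50 changed 1.5-fold, and 7.29% of its calls were unchanged genes, more than the threshold of 0.05 allows on average. The simulation was run after a first look at the real data.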

Results

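RNA was sequenced from wing imaginal discs, the larval epithelium that forms the adult wing and notum, of Drosophila melanogaster at the wandering stage of the third larval instar. The discs came from yw larvae, the wildtype here, and from yw larvae carrying nub[1], an allele of nubbin. Each genotype had 3 libraries. Total counts were 61981014, 58434785 and 82407049 in wildtype replicates 1 to 3 and 72134981, 76042164 and 83448836 in nub1 replicates 1 to 3. Nothing in the labels says that replicates came from separate larvae or crosses, so p-values measure only the spread between these libraries, which may be technical.

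The targeted gene was examined first. Counts of nub, a POU domain transcription factor of the wing (FBgn0085424, dm6 chromosome arm 2L, 12587625 to 12628135), were 329 ± 12.2 CPM in wildtype and 10.9 ± 3.09 CPM in nub1 discs (SD, n = 3). The log2 fold change was -4.92 ± 0.25 (SE; edgeR adjusted p = 0.000158), and all 3 nub1 libraries lay below all 3 wildtype libraries. Its neighbouring paralog pdm2 (FBgn0004394, 2L, 12657165 to 12686306) fell further, with 57.1 ± 0.394 CPM in wildtype and 0.107 ± 0.0426 CPM in nub1 discs (SD, n = 3) and a log2 fold change of -9.04 ± 0.09 (edgeR adjusted p = 6.88e-11). The zinc finger gene rn, whose tagged protein was used for the ChIP-seq of the same series, fell by less, from 264 to 204 CPM (log2 fold change -0.37 ± 0.04; edgeR adjusted p = 5.08e-05). Of the other POU domain genes, pdm3 rose (log2 fold change 0.96 ± 0.04) and vvl fell (-0.49 ± 0.03), while acj6 was too low to test. The list was called lower as a whole (camera adjusted p = 0.00928; adjusted p = 0.510 with an estimated correlation; adjusted p = 0.103 with limma-voom), and it includes the targeted gene. Ref2 overlaps nub and Nepl7 lies within pdm2, and the strand setting of the counting is not given in the sources used here, so reads of overlapping genes cannot be separated.

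**Figure D1:**
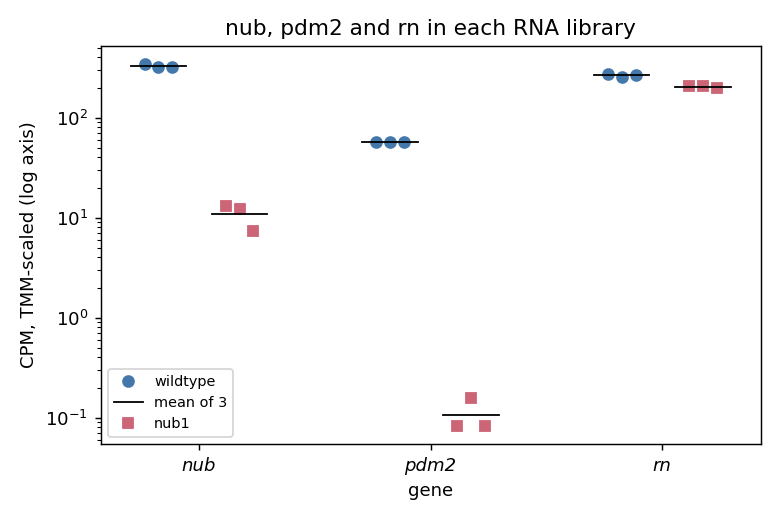
CPM (TMM-scaled, log axis) of nub, pdm2 and rn, with 1 point per library and a line at the mean of 3 libraries. The nub means were 329 CPM in wildtype and 10.9 CPM in nub1 discs, and the rn means were 264 and 204 CPM.

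Across the transcriptome, 2239 genes were higher and 2195 lower in nub1 discs among 9186 tested (edgeR quasi-likelihood, adjusted p under 0.05). These were 24.4% and 23.9% of the tested genes, and the list counts below are to be read against these shares. The balance depended on the scaling, with 2675 higher and 1815 lower with library sizes only, and 2469 and 1942 with the upper quartile. Changes of at least 2-fold were found in 506 genes in the upward and 435 in the downward direction, and 66.9% of the called genes differed by less than 1.5-fold. The largest rises included mthl8, a methuselah-like receptor gene, and Gr64a, a gustatory receptor gene. Neither had a count in a wildtype library, and against a floor of 3 counts over the group they were at least 2901-fold and 1035-fold higher. Ir76a, an ionotropic receptor gene, rose from 0.0190 to 16.5 CPM, miple1 from 3.22 to 128 CPM, CG6414 from 0.761 to 90.0 CPM, tor from 0.398 to 16.8 CPM, unc79 from 0.367 to 12.2 CPM and CG11594 from 0.0829 to 24.9 CPM. Among the largest falls were the cytochrome P450 genes Cyp4p1 (39.8 to 0.0161 CPM) and Cyp4p2 (194 to 0.133 CPM), CG15236 (55.5 to 0.0256 CPM), CG33509 (17.6 to 0.0252 CPM), the sodium channel family gene ppk13 (34.1 to 0.0645 CPM), unc-13-4A (20.6 to 0.0438 CPM), the kinesin gene Klp54D (12.4 to 0.0253 CPM) and CG6912 (24.7 to 0.155 CPM). Oseg5 had 3 counts over the nub1 libraries (0, 3 and 0 in replicates 1 to 3) and was 882-fold lower, with a 95% counting interval of 301 to 4278. Cyp4p1 and Cyp4p2 are similar neighbours, and Ir76a, CG11594, CG6414, unc79, Cyp4p1, Cyp4p2, CG15236, Oseg5 and CG6912 overlap another annotated gene, so their values are uncertain. Several low means fell when 1 library was left out, although other libraries held counts too. Without nub1 replicate 2 the nub1 means were 0.00588 CPM for CG15236, 0.0118 for CG33509, 0.0687 for Cyp4p2 and 0.0266 for unc-13-4A. Without nub1 replicate 3 that of Cyp4p1 was 0.00651 CPM. The wildtype means were 0.398 CPM for CG6414 without wildtype replicate 2 and 0.0122 for Ir76a without wildtype replicate 1. A filter of at least 5 CPM in at least 3 libraries left 141 genes at least 2-fold higher and 120 lower.

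Genes of the wing pouch, the part of the disc that forms the wing blade, were mostly lower. In this list 4 of 16 tested members rose and 10 fell (4 and 10 adjusted over the list alone). The transcription factor kn, which patterns the central intervein, fell from 55.2 to 5.33 CPM (log2 fold change -3.38 ± 0.06), the corepressor nab from 98.0 to 23.3 CPM (-2.07 ± 0.09) and dve from 116 to 33.2 CPM (-1.80 ± 0.05). The log2 fold changes of bs, which marks intervein cells, Dll and fj were -1.07 ± 0.12, -0.92 ± 0.07 and -0.88 ± 0.03, and vg, the wing selector, fell by less (-0.27 ± 0.03). In the other direction elB rose (0.41 ± 0.03), as did bi, noc and salm with smaller changes (0.17, 0.18 and 0.13; edgeR adjusted p = 0.0496 for salm), while sd did not pass the test (-0.06 ± 0.03). The noc call was lost without wildtype replicate 2 or 3 or nub1 replicate 1 (edgeR adjusted p = 0.0949, 0.0857 and 0.0561). The salm call was lost without wildtype replicate 2 or 3 or nub1 replicate 1 or 2 (edgeR adjusted p = 0.157, 0.140, 0.146 and 0.0850). The list was called lower (camera adjusted p = 3.33e-05), but not with the correlation between genes estimated (adjusted p = 0.510 with an estimated correlation). Of wing pouch members, 2 rose without wildtype replicate 2 or 3 or nub1 replicate 1.

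In the wing hinge list, 6 of 12 tested members rose and 3 fell (6 and 4 adjusted over the list alone). Sox15 rose from 145 to 294 CPM (log2 fold change 1.02 ± 0.05), zfh2 from 825 to 1267 CPM (0.62 ± 0.03) and the cadherin gene ds from 1138 to 1549.5 CPM (0.45 ± 0.04). The T-box genes Doc1 and Doc2 fell, by 1.83 ± 0.04 and by 1.65 ± 0.05 on the log2 scale. In the notum list 4 of 12 tested members rose and 1 fell (4 and 1 adjusted over the list alone), led by tup (0.42 ± 0.03) and caup (0.28 ± 0.03). Among Hox genes, 2 of 4 tested members rose and 1 fell (2 and 1 adjusted over the list alone). Of these, Antp rose by 0.11 on the log2 scale and Scr from 1.15 to 2.75 CPM, while lab fell (edgeR adjusted p = 0.0494). The Antp call was lost without wildtype replicate 2 or 3 or nub1 replicate 1 (edgeR adjusted p = 0.0575, 0.0533 and 0.0690). The lab call was lost without wildtype replicate 1, 2 or 3 or nub1 replicate 1, 2 or 3 (edgeR adjusted p = 0.112, 0.0600, 0.151, 0.0784, 0.120 and 0.133). It was also lost with the DESeq2 Wald test (0.237), the replicate block (0.0784), no filter (0.114), each other scaling (0.0513 to 0.0651) and the 20 most abundant genes left out (0.0501). Neither the hinge (camera adjusted p = 0.710), the notum (camera adjusted p = 0.292) nor the Hox list (camera adjusted p = 0.614) was called. For the hinge list the mean (-0.12) and the median (0.13) log2 fold change differed in sign. Of notum members, 0 fell without wildtype replicate 1 or 2 or nub1 replicate 2, and 2 fell without nub1 replicate 1. Of Hox members, 1 rose without wildtype replicate 2 or 3 or nub1 replicate 1, and 0 fell without wildtype replicate 1 or 2 or nub1 replicate 1, 2 or 3.

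**Figure D2:**
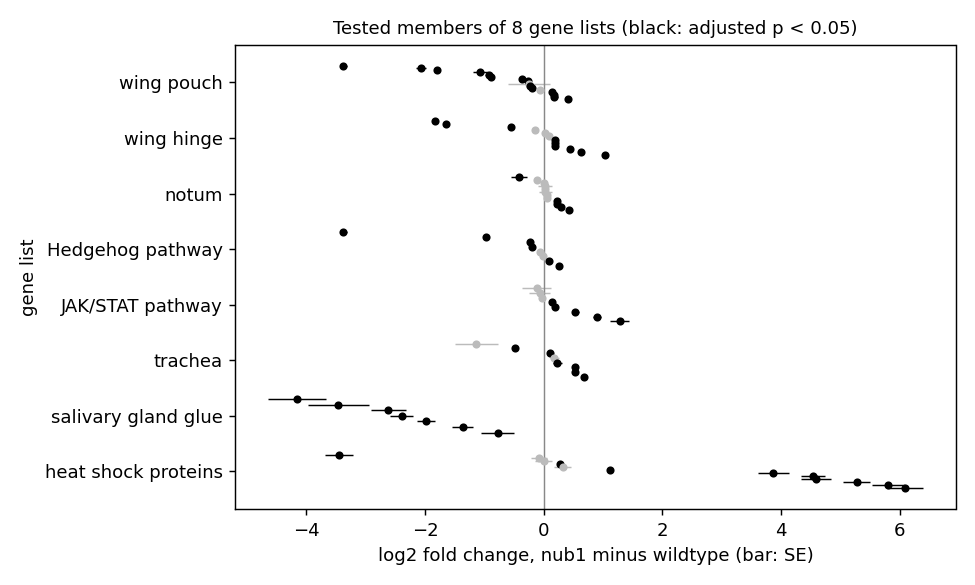
Log2 fold change (nub1 minus wildtype, horizontal axis) of each tested member of 8 gene lists, with bars of 1 SE, black where the adjusted p was under 0.05 and grey otherwise. In the wing pouch list kn lies lowest at -3.38 and elB highest at 0.41.

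Signalling genes changed in part. In the wing margin and Wingless list 2 of 14 tested members rose and 9 fell (2 and 10 adjusted over the list alone): sens, a proneural zinc finger gene, fell from 8.16 to 1.53 CPM (-2.42 ± 0.20), Wnt4 from 23.5 to 8.77 CPM and wg from 119.6 to 89.2 CPM, and the receptor gene fz rose (0.31 ± 0.03). The list was called lower (camera adjusted p = 0.0260; adjusted p = 0.801 with an estimated correlation), but not with the stricter filter (adjusted p = 0.108). In the Hedgehog list 2 of 8 tested members rose and 4 fell (2 and 4 adjusted over the list alone). Besides kn, the posterior selector en fell from 93.6 to 47.8 CPM (-0.97 ± 0.04) and ci rose (0.26 ± 0.03), and the list was called lower (camera adjusted p = 0.0329; adjusted p = 0.510 with an estimated correlation). The mean of the Hedgehog list (-0.56) lay well below its median (-0.13), the largest fall being that of kn (-3.38), also a pouch member. The list was not tested without kn. In the JAK/STAT list 5 of 8 tested members rose and 0 fell (5 and 0 adjusted over the list alone), with the ligand gene upd1 rising from 6.60 to 12.2 CPM, upd3 from 0.680 to 1.66 CPM and Socs36E from 85.4 to 123 CPM. It was called higher (camera adjusted p = 0.0448; adjusted p = 0.510 with an estimated correlation). The Hedgehog call was lost without wildtype replicate 1 or 2 (adjusted p = 0.0708 and 0.0719). The JAK/STAT call was lost without wildtype replicate 1 or 2 or nub1 replicate 2 or 3 (adjusted p = 0.0552, 0.0749, 0.0533 and 0.128). Of wing margin members, 1 rose without nub1 replicate 1 or 2. Of Hedgehog members, 1 rose without wildtype replicate 2 or 3 or nub1 replicate 1 or 3.

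Among EGFR pathway genes 3 of 10 tested members rose and 5 fell (3 and 5 adjusted over the list alone), including falls of rho (-1.65 ± 0.10) and spi (-0.64 ± 0.05) and a rise of kek1 (0.34 ± 0.03). For Dpp pathway genes 6 of 13 tested members rose and 2 fell (6 and 2 adjusted over the list alone), with put at -0.23 and brk at 0.21. For the E(spl) targets of Notch 0 of 12 tested members rose and 3 fell (0 and 2 adjusted over the list alone), with E(spl)mgamma-HLH at -0.41 ± 0.09. The call of E(spl)m2-BFM was lost without wildtype replicate 1 or 2 or nub1 replicate 2 or 3 (edgeR adjusted p = 0.124, 0.107, 0.108 and 0.0710) and with no filter (0.104). That of E(spl)mdelta-HLH was lost without wildtype replicate 1 or nub1 replicate 2 (edgeR adjusted p = 0.0600 and 0.0604). In the Hippo and Fat/Dachsous list 2 of 16 tested members rose and 7 fell (2 and 7 adjusted over the list alone), among them fj and Diap1 (-0.38 ± 0.04). None of these lists was called with all libraries, with camera adjusted p values of 0.614 (EGFR), 0.688 (Dpp), 0.380 (E(spl)) and 0.255 (Hippo). The E(spl) list was called without nub1 replicate 1 (adjusted p = 0.0310; 0.0310 to 0.862 over the alternatives), and fry called the Hippo list (adjusted p = 0.00976). Of Dpp members, 3 rose without wildtype replicate 2 or 3 or nub1 replicate 1. Of E(spl) members, 1 fell without wildtype replicate 1 or nub1 replicate 2, and 8 fell without nub1 replicate 1.

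Most tested heat shock genes rose, and most of those that rose started from low levels. In this list 8 of 12 tested members rose and 1 fell (8 and 1 adjusted over the list alone), and it was called higher (camera adjusted p = 5.14e-06; adjusted p = 0.510 with an estimated correlation). Hsp68 rose from 8.12 to 188 CPM and the cochaperone DnaJ-1 from 156 to 338 CPM, while Hsp23, at 2115 to 2109 CPM, did not pass the test and Hsp67Bc fell (-3.45 ± 0.24). The Hsp70 copies rose too, Hsp70Bb from 0.163 to 11.6 CPM, but they are near-identical and their separate values are uncertain. Hsp70Aa, Hsp70Ab, Hsp70Bb and Hsp70Bc were among the 8 rises. The count of rises and the camera call, which takes members as nearly independent, may thus count the same reads several times. In the JNK and stress list 9 of 17 tested members rose and 6 fell (9 and 6 adjusted over the list alone), with Gadd45 rising from 11.5 to 38.8 CPM, Xrp1 from 528 to 718 CPM and GstE1 falling from 15.6 to 6.87 CPM (camera adjusted p = 0.490). For apoptosis genes 1 of 7 tested members rose and 5 fell (1 and 5 adjusted over the list alone): rpr rose (0.55 ± 0.06) and Diap1 and Dcp-1 fell (camera adjusted p = 0.211). For cell cycle genes 13 of 22 tested members rose and 1 fell (14 and 2 adjusted over the list alone), with stg and dap at 0.39 and 0.46 and aurB at -0.42 (camera adjusted p = 0.0695). The cell cycle list was called with limma-voom (adjusted p = 0.0272), with the replicate block (0.0318), without wildtype replicate 3 (0.0184) and without nub1 replicate 1 (0.0310), and the alternatives ranged from 0.0184 to 0.855. Of apoptosis members, 3 fell without wildtype replicate 1 or nub1 replicate 2. Of cell cycle members, 2 fell without wildtype replicate 2 or nub1 replicate 3.

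Ecdysone response and staging genes moved in both directions: 11 of 26 tested members rose and 7 fell (12 and 7 adjusted over the list alone), and the list was not called (camera adjusted p = 0.622). The list was not divided by stage, so camera could miss a stage shift that moves its members in opposite directions. ImpE2 fell from 4519 to 1474 CPM and Eip78C from 121 to 37.1 CPM, while chinmo rose from 24.3 to 80.0 CPM and Edg91 from 2.49 to 5.56 CPM. The ImpE2 call was lost without wildtype replicate 1, 2 or 3 or nub1 replicate 1 or 2 (edgeR adjusted p = 0.103, 0.103, 0.0774, 0.0765 and 0.0740). The Eip78C call was lost without wildtype replicate 1, 2 or 3 or nub1 replicate 1 or 2 (edgeR adjusted p = 0.0962, 0.0907, 0.0692, 0.0648 and 0.0811). The chinmo call was lost without wildtype replicate 1 or 2 or nub1 replicate 2 (edgeR adjusted p = 0.0580, 0.0503 and 0.0511). Replicates spread widely for several of them, such as Hr4, at 253 ± 66.5 CPM in wildtype and 69.5 ± 56.9 CPM in nub1 discs (SD, n = 3), which did not pass the test (edgeR adjusted p = 0.256) but was called without nub1 replicate 3 (edgeR adjusted p = 0.0397). Of ecdysone members, 7 rose without wildtype replicate 1 or nub1 replicate 2, 3 fell without wildtype replicate 2, and 4 fell without wildtype replicate 1 or 3 or nub1 replicate 1 or 2.

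Markers of other cell types were measured in the same libraries. For myoblasts, the muscle precursors that adhere to the notum, 5 of 9 tested members rose and 2 fell (5 and 2 adjusted over the list alone), with htl rising (0.67 ± 0.03) and Ama falling (-0.83 ± 0.05; camera adjusted p = 0.211). For trachea 5 of 8 tested members rose and 1 fell (5 and 2 adjusted over the list alone), with the chitin deacetylase genes verm and serp at 0.68 and 0.52 and trh at -0.49 (camera adjusted p = 0.112). For haemocytes 4 of 12 tested members rose and 3 fell (5 and 3 adjusted over the list alone), with the collagen genes vkg and Col4a1 rising by 1.17 and 1.05 on the log2 scale (camera adjusted p = 0.453). For fat body 2 of 8 tested members rose and 2 fell (2 and 2 adjusted over the list alone), with Lsp1alpha rising from 0.546 to 4.84 CPM and Fbp1 falling from 13.6 to 1.92 CPM (camera adjusted p = 0.688). The Fbp1 call was lost without nub1 replicate 1 or 3 (edgeR adjusted p = 0.0532 and 0.0540). For the fat body list the median (-0.22) lay below 0 while camera pointed up, and for haemocytes the median (-0.02) and mean (0.24) differed in sign. For salivary gland glue 0 of 7 tested members rose and 7 fell (0 and 7 adjusted over the list alone), all at low levels, Sgs7 falling from 3.11 to 0.785 CPM (camera adjusted p = 3.33e-05; adjusted p = 0.510 with an estimated correlation). For differentiated muscle 6 of 10 tested members rose and 0 fell (6 and 0 adjusted over the list alone), with Mlc2 rising from 9.40 to 24.1 CPM (camera adjusted p = 0.0419; adjusted p = 0.652 with an estimated correlation). For sensory organ precursors and neurons 4 of 11 tested members rose and 4 fell (4 and 4 adjusted over the list alone), with ac at 0.36 ± 0.05 besides the fall of sens, and the list was not called (camera adjusted p = 0.688). For antimicrobial peptides and immune genes 4 of 5 tested members rose and 0 fell (5 and 0 adjusted over the list alone), the largest being CecB, with 0 wildtype and 46 nub1 counts and at least 13.1-fold higher (camera adjusted p = 0.0419; adjusted p = 0.510 with an estimated correlation). Only 5 of the 18 members fixed were tested, and those that rose had nub1 means of at most 1.08 CPM. CecB and PGRP-SB1, with 0 and 7 wildtype counts, passed the filter on low counts through the nub1 libraries alone. That selection favours rises, so the count and the call of this list are weak evidence. The PGRP-LB call (edgeR adjusted p = 0.0484), 1 of the 4 rises in the immune list, was lost without wildtype replicate 2 or 3 or nub1 replicate 1, 2 or 3 (edgeR adjusted p = 0.123, 0.172, 0.107, 0.0887 and 0.0964). It was also lost with the DESeq2 Wald test (0.195), the replicate block (0.0563) and no filter (0.0695). The muscle call was lost without wildtype replicate 1 or 2 or nub1 replicate 2 or 3, at adjusted p = 0.0552, 0.0719, 0.0533 and 0.125. The immune call was lost without wildtype replicate 2 or nub1 replicate 3, at adjusted p = 0.0548 and 0.232. Without robust estimation, with the replicate block and with scaling by upper quartile or library size, the JAK/STAT, muscle and immune calls were lost too (adjusted p = 0.152, 0.104 and 0.172 without robust estimation). The JAK/STAT, muscle and Hedgehog calls were lost with limma-voom, and those of JAK/STAT and muscle with the stricter filter. The immune call was lost with no filter (camera adjusted p = 0.419), and that of the wing margin list without robust estimation (adjusted p = 0.0796). The pouch, glue and heat shock calls were lost only with an estimated correlation, but the stricter filter left too few glue and immune genes to test those lists. Of myoblast members, 1 fell without wildtype replicate 1 or 2. Of trachea members, 3 rose without wildtype replicate 2 or 3 or nub1 replicate 2, and 2 fell without nub1 replicate 3. Of haemocyte members, 1 fell without nub1 replicate 1, 2 or 3. Of fat body members, 1 fell without nub1 replicate 1 or 3, and 4 fell without wildtype replicate 3. Of muscle members, 1 fell without wildtype replicate 2.

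For sex-linked markers 0 of 7 tested members rose and 0 fell (0 and 0 adjusted over the list alone) by edgeR, with 2 at an unadjusted p under 0.05 and 0 called by DESeq2 (camera adjusted p = 0.614). The male-specific RNA roX1 stood at 818, 295 and 263 CPM in wildtype replicates 1 to 3 and at 471, 500.2 and 568 CPM in the nub1 libraries. Its log2 fold change was 0.16 ± 0.53 with all libraries and 0.89 ± 0.10 without wildtype replicate 1 (edgeR adjusted p = 0.00333). On the same omission roX2 (1.05; edgeR adjusted p = 0.000303) and Sxl (-0.16; 0.0350) were called too. Of sex-linked marker members, 2 rose without wildtype replicate 1, and 1 fell without wildtype replicate 1.

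Called genes were found on all chromosome arms, with the highest shares on 2R (51.8%) and 2L and the lowest on arm 4 (33.7%). On 2L, which carries nub, 51.7% of 1583 tested genes were called, against 47.5% on the other arms, an odds ratio of 1.18 (95% interval 1.06 to 1.32; two-sided Fisher's exact test, p = 0.00256). On X the share was 43.3%, against 49.3% on the autosomes (odds ratio 0.786; two-sided Fisher's exact test, p = 1.67e-05). For calls of at least 2-fold, a planned setting, the 2L odds ratio was 1.19 (95% interval 0.997 to 1.42; two-sided Fisher's exact test, p = 0.0498). The 2L difference did not pass with no filter on low counts (odds ratio 1.06) or with the stricter filter (1.13). These filter settings were not planned for the odds ratio.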

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

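No called value among the genes named by rule, the lists and the 2L and X odds ratios changed direction under the alternatives, most of them chosen before the data were examined. Single values of genes named as examples were followed only with 1 library left out. Same-numbered libraries correlated at 0.0426, 0.0346 and 0.248 in their deviations, for numbers 1 to 3. The value for number 3 was the highest of all pairs of a wildtype and a nub1 library. Libraries numbered 3 correlated negatively with those of the other genotype numbered 1 or 2 (-0.193 to -0.0962). The deviations of each gene cancel within a genotype, so the positive value for number 3 forces negative ones, which are no further evidence. Given the value of 0.248, an effect shared by the libraries numbered 3 cannot be excluded, and the labels do not say whether the numbers mark a batch. With the replicate block, 2451 genes were higher and 2437 lower, and 7 lists were called. Leaving out 1 library gave 1827 to 2094 genes higher, 1726 to 1995 lower, 492 to 536 at least 2-fold higher and 415 to 455 at least 2-fold lower, and 5 to 11 lists called, the fewest without wildtype replicate 2. Without both libraries numbered 3, a choice made after seeing the data, 1959 genes were higher and 1951 lower, and 6 lists were called. In that setting the JAK/STAT, muscle and immune list calls were lost (camera adjusted p = 0.177, 0.281 and 0.314). The calls of lab, PGRP-LB and E(spl)mdelta-HLH were lost too (edgeR adjusted p = 0.255, 0.240 and 0.0635). The stricter filter, which tests fewer genes, left 141 genes at least 2-fold higher, 120 lower and 4 lists. At adjusted p under 0.01, 1549 genes were higher and 1418 lower. The number of lists called was 5 without robust estimation, 0 with an estimated correlation and 15 with fry. The 2L odds ratio was 1.06 with no filter and 1.13 with the stricter filter, settings not planned for it. Except where the filter sets the number of genes, the cause was not tested. For the genes named by rule other than nub, pdm2 and rn, 36 single-gene values lost and 2 gained a call, against 1859 that did neither. Calls of lab, PGRP-LB and E(spl)m2-BFM were among those lost. Genes named as examples were left out of this tally. Depth limits genes at or under 3 counts in a group.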

Other observations

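The tests of the 2L odds ratio, roX RNAs and sample splits were chosen before the values were seen; those of male share as the whole cause, of the pouch list and of the nub residue were chosen after. Around nub, the flanking genes CCT4 and bun were measured at 480.4 to 482 CPM and 399 to 467 CPM, bun being called higher (log2 fold change 0.23 ± 0.04; edgeR adjusted p = 0.00123). Between bun and nub, lncRNA:CR44596 had 21 wildtype and 2 nub1 counts (12.3-fold lower, 95% counting interval 3.00 to 108) and lncRNA:CR44595 19 and 1 (22.2-fold lower, 95% counting interval 3.53 to 922), both too low to test. Nepl7, which lies within pdm2, had 106 counts over the wildtype and 0 over the nub1 libraries. From the start of nub to the end of pdm2 the interval spans 98.7 kb. Among the genes with the largest changes, 3 pairs were close neighbours moving the same way: CG33509 and ppk13, Cyp4p2 and Cyp4p1, and CG11594 and Gr64a, separated by 284, 210 and 758 bp.

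The number of called genes, 4434, was weighed first. Among the 10 splits of the 6 libraries into 3 and 3, 1 gave as many by edgeR, and the highest of the others gave 0. The others gave 20 to 169 genes at an unadjusted p under 0.05, and up to 3 by DESeq2. Each of the other splits mixes genotypes, so the genotype difference widens the spread within its groups and few calls were likely beforehand. Also, 10 splits are too few for a share under 0.05, so the splits cannot decide. The odds ratio of 1.18 for 2L, upper limit 1.32, argues against background acting on genes of 2L alone as the main source. It does not bear on 2L background that changes genes of other arms. The arms compared with 2L include 2R of the same chromosome, where 51.8% of tested genes were called, which lowers the ratio. Shares on 2L and 2R were the highest of all arms, also for calls of at least 2-fold (11.6% and 12.1%, against 7.39% to 10.4% elsewhere). Most of the 10 largest falls lay on 2L or 2R, while most of the 10 largest rises did not. Background on 2R and the other arms stays open, since no second strain was tested. A different share of male larvae as the whole cause is also argued against. With wildtype replicate 1 left out, roX1 and roX2 were at most 2.48-fold higher in a nub1 than in a wildtype library, while 251 of the 2239 genes called higher rose by more than this between each pair of such libraries. The test takes roX levels to follow the male share, and bears on rises alone. A part of male share in smaller rises and in falls cannot be told apart from genotype: roX1 and roX2 had log2 fold changes of 0.16 and 0.40, and 0.89 and 1.05 without wildtype replicate 1, when Sxl was called lower (-0.16). Loss of nub and pdm2 function stays open as an untested biological explanation.

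A smaller pouch could lower the counts of pouch genes. If the list members were expressed in the pouch alone, a smaller pouch as the whole cause would lower all of them. Yet 4 members (bi, salm, elB and noc) had unadjusted 95% intervals above 0 and 10 had intervals below 0. With 1 library left out 3 to 4 lay above, salm being the member lost without wildtype replicate 2 or 3 or nub1 replicate 1. Expression outside the pouch was not measured, and a smaller pouch would raise the share of other tissue in CPM. For members also expressed elsewhere the test therefore cannot decide. A smaller pouch, alone or together with changes within its cells, stays open. A difference in larval stage stays open too, since no value separated it from genotype: in the ecdysone response and staging list 11 members rose and 7 fell (camera adjusted p = 0.622), all 7 tested glue genes fell (6 to 7 with 1 library left out), and Ilp8 rose from 0.0360 to 1.52 CPM (log2 fold change 5.39 ± 0.88; edgeR adjusted p = 0.00368; nub1 mean 0.943 CPM without nub1 replicate 3). With 1 library left out, 7 to 11 staging genes rose and 3 to 9 fell, the fewest falls being without wildtype replicate 2. The list was not divided into genes of earlier and later stages. These counts and camera therefore cannot show a shift that moves such genes in opposite directions.

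Some nub counts were left in the nub1 libraries, at 2.24% to 3.99% of the wildtype mean per library. Wildtype tissue mixed into the nub1 libraries would leave nub and pdm2 at the same share, yet 3.27% of nub and 0.187% of pdm2 was left (95% counting interval of pdm2 0.121% to 0.276%). Remaining nub transcription and reads from other POU genes may both contribute, and no test separated them.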
